A study of Mus musculus with 4 samples.

How the data were processed

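Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on lungs of mouse embryos at embryonic day 15.5 that carried a FLAG epitope on HOXA5 at both alleles of the endogenous gene. HOXA5 is a homeodomain transcription factor encoded in the HOXA cluster. According to the labels, tissue was fixed in 1% formaldehyde for 10 min, chromatin was sheared to between 200 and 500 bp, and 20 µg of it was incubated with an anti-FLAG antibody. Libraries were prepared from 2 ng of DNA. The series holds 4 libraries, which are 2 immunoprecipitates and 2 inputs. Peak lists of the 2 immunoprecipitates were used, and the inputs were not analysed here, so immunoprecipitate and input were not compared. The sample titles carry the abbreviation wt although the genotype label gives the tagged allele, and the peak names inside the replicate 2 list carry another replicate number than its label. The labels were followed in both cases, and no untagged control was analysed here. The labels do not say whether the replicates came from separate litters or pools of lungs, so agreement between them may be technical in part.

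The authors deposited 1 peak list per immunoprecipitate, so peaks were called per replicate and not on pooled reads. Per the submitters' processing notes, the tools were FastQC 0.12.1, Trim Galore, Bowtie2 2.5.2, SAMtools 1.18, bedtools 2.31.0, MACS3 3.0.1 and deepTools, with the mm10 build. The order of the steps, their settings, the control given to the peak caller and any filter on problem regions are not given in the sources used here. Each row of the deposited lists gives a fold enrichment at the summit, which is a ratio by the authors' peak caller. The deposited −log10 p and −log10 q at the summit are the authors' values too, and every −log10 q lay above 2. The deposited score was the whole part of 10 times −log10 q in over 99% of rows and was not used. Fold and −log10 q belong to a peak within its own list. They served to describe, rank and filter peaks in that list, and no change between replicates was read from them. The lists hold no read counts, so the sequencing depth is unknown. A difference in depth would change how many peaks pass a threshold.

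Peaks of the 2 lists were called shared when they overlapped by at least 1 bp, and chains of overlapping peaks were merged into 1 shared peak, placed at the summit of its replicate 1 member. The overlap was compared with 100000 random placements of the replicate 2 peaks within their own chromosomes (one-sided permutation test). Shares carry 95% Wilson intervals, which treat peaks as independent.

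Genes came from a RefSeq gene table of the GRCm38.p6 assembly, which is the mm10 build of the lists. The table gives the start and end of each gene but no strand, exons or sequence. The planned test of distance to transcription starts was therefore replaced by distance to either annotated end of a gene, called a gene boundary here. Exons, introns and untranslated regions were not told apart, and the planned motif test was not run. Of 49943 genes on the assembled chromosomes, 340 with a start below 3 Mb on a chromosome other than Y were left out. Those coordinates were taken to be positions on scaffolds. The remaining 49603 genes, 21779 of them protein-coding, were used. Summits were classed as within 1000 bp of a gene boundary, elsewhere in a gene body, or intergenic, and each share was set against the share of bases in that class (exact binomial test, two-sided, with Benjamini-Hochberg adjustment over the 3 classes). All bases between the first and last gene of a chromosome were counted, assembly gaps included. The plan was to leave out bases of unknown sequence, but no sequence was used here. Peaks with and without a partner were compared within each list by Fisher's exact test, two-sided.

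A shared peak was assigned to the protein-coding gene holding its summit, otherwise to the gene with the nearest boundary within 100 kb. For 22 gene lists fixed before the data were examined, the number of members with a shared peak was compared with 100000 random lists of the same size, matched on the decile of the bases that would be assigned to each gene (two-sided permutation test, Benjamini-Hochberg adjustment over the lists). The lists covered Hox genes, TALE cofactors, lung mesenchyme transcription factors, lung epithelium, smooth muscle, cartilage, endothelium, pericytes, mesothelium, nerve, blood, liver, 6 signalling pathways, extracellular matrix, cell cycle, ribosomal proteins and olfactory receptors. Random lists treat genes as independent, which neighbouring genes are not.

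Genes named in the text are those nearest to the 15 shared peaks with the best mean rank of −log10 q, up to 4 members of each list by the same rank, every Hox gene and TALE cofactor with a shared peak, and Hoxa5 itself. Some genes that this rule selects are not reported here. That rule, the main tests and most alternatives were also set before the data were examined. The comparisons of peaks by fold enrichment, with their cuts, were not part of that plan. Substituting gene boundaries for transcription starts, and setting apart peaks longer than 1000 bp, were decided afterwards. Alternatives covered the overlap rule, a −log10 q of at least 5, the top 1000 peaks, autosomes and X, local random shifts, other distances, protein-coding genes alone, each replicate alone and unmatched gene lists.

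The procedures were tested on simulated data. All 1500 planted pairs were found among 4000 simulated peaks, with 2 further pairs. Of 200 unrelated lists 0.5% had a p below 0.05, and 100% of 100 lists with 9 bound members of 30 did, each drawn from 21779 genes. Both rates are for p before adjustment over the lists, and how often such lists pass after adjustment was not simulated. The first rate is far below the threshold, so the list test was conservative. Simulated members were drawn at random, so lists of neighbouring genes such as Hox clusters were not covered. Smaller excesses were not simulated, so a list that did not pass may still hold one. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were made with matplotlib 3.10.9.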

Results

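HOXA5 occupancy was measured in lungs of E15.5 mouse embryos with a FLAG tag on HOXA5, in 2 immunoprecipitates. Replicate 1 had 4289 peaks with a median length of 414 bp and a median fold enrichment of 3.87 (range 1.28 to 58.1). Replicate 2 had 2832 peaks with a median length of 436.5 bp and a median fold of 3.36 (range 1.16 to 25.6). Fold enrichment and −log10 q are the authors' values for each peak in its own list. The read depth of the libraries is unknown. All positions are in mm10.

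The first comparison asked which HOXA5-FLAG peaks were found in both replicates. Of the replicate 2 peaks, 2197 (77.6%, 95% Wilson interval 76.0 to 79.1) overlapped a replicate 1 peak, and of the replicate 1 peaks, 2195 (51.2%, 49.7 to 52.7) overlapped a replicate 2 peak. They formed 2175 shared peaks. Random placement of the replicate 2 peaks on the assembled chromosomes gave 6.30 overlaps on average (SD 2.51) and at most 20. Observed there were 2179 (one-sided permutation p = 1e-05, the smallest that 100000 placements can give). Regions of high background common to both libraries would overlap too, so this test cannot tell binding from background. The summits of shared peaks lay a median of 32 bp apart, and 1587 of the 2175 (73.0%) were within 100 bp of each other.

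Replicate 1 peaks of at least 10-fold and replicate 2 peaks of at least 5-fold were found in both replicates more often than the others. Of 249 replicate 1 peaks of at least 10-fold, 244 (98.0%, 95.4 to 99.1) had a partner, against 1951 of 4040 (48.3%, 46.8 to 49.8) below 10-fold. In replicate 2, 440 of 442 peaks of at least 5-fold (99.5%, 98.4 to 99.9) had a partner, against 1757 of 2390 (73.5%, 71.7 to 75.2) below. These cuts were not planned and differ between the lists. With the cut at 5-fold the replicate 1 shares were 71.2% and 43.4%, and with the cut at 10-fold the replicate 2 shares were 100% and 77.0%. The share did not rise steadily, being 60.6% at 1- to 2-fold and 41.7% at 3- to 4-fold in replicate 1, and 66.0% at 1- to 2-fold and 59.0% at 2- to 3-fold in replicate 2. Within replicate 1 the median fold was 4.21 for shared and 3.63 for unshared peaks, and within replicate 2 it was 3.62 and 2.78 (two-sided permutation p = 1e-05 for the mean log2 fold in each list, the smallest value possible).

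**Figure D1:**
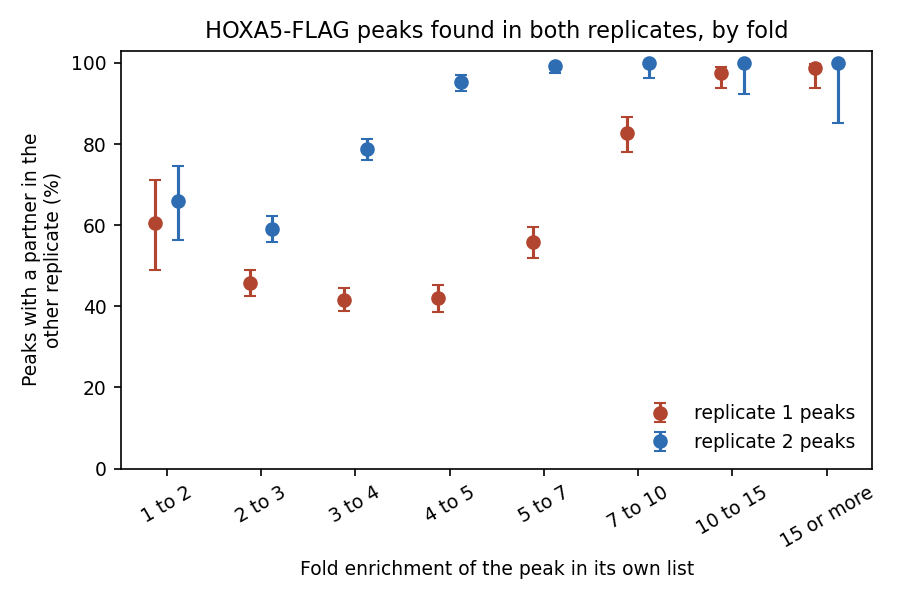
Share of HOXA5-FLAG peaks with an overlapping peak in the other replicate (y axis, %) against the peak's fold enrichment in its own list (x axis, unequal bins), for replicate 1 and replicate 2, with 95% Wilson intervals. The share reached 97.5% in replicate 1 at 10- to 15-fold and 95.4% in replicate 2 at 4- to 5-fold.

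The best-ranked shared peaks were of 2 kinds. Of the 15 with the best mean rank of −log10 q, 10 had folds above 20 in replicate 1 and a length of at most 720 bp. The highest lay inside 2700097O09Rik (chromosome 12, 55060815 to 55061534), with 54.4-fold enrichment in replicate 1 and 25.6-fold in replicate 2. Il21r, the interleukin 21 receptor gene, held a peak at chromosome 7, 125632198 to 125632853, with 50.5- and 21.2-fold enrichment. A peak 62.6 kb from E2f3, a cell cycle transcription factor gene (chromosome 13, 30048313 to 30048980), had 42.8 and 19.7. Disp1, which encodes a protein needed to release hedgehog ligands, had a peak 13.6 kb outside the gene (chromosome 1, 183072344 to 183072936) with 37.3 and 21.2. Peaks inside Plekha5, Gyg, Itpr1, Trps1 and Ablim1, and one 14953 bp from Gm5174, had between 21.8- and 36.4-fold enrichment in replicate 1. The other 5 had folds of 4.14 or less in both lists, so their rank came from a high −log10 q and not from a high fold. They included a peak of 37636 bp in replicate 1 at the start of the assembled part of chromosome 9 (3000330 to 3037967, 311 kb from Alkbh8), one of 45815 bp on an unplaced scaffold, and one each 164 kb from Tcte2 and 35.7 kb from Zfp825. The last of these, of 492 bp and 124 kb from Fgf14 on chromosome 14, had 2.21- and 1.83-fold enrichment with −log10 q of 457 and 300. At the chromosome 9 peak −log10 q was 14579 in replicate 1 and 5968 in replicate 2, at 2.85- and 1.87-fold. Without the inputs, such peaks cannot be told from regions of high background.

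Shared peaks were next set against gene positions. Of 2144 shared peaks within the annotated parts of the chromosomes, 129 (6.02%, 5.09 to 7.10) had their summit within 1000 bp of a gene boundary, against 6.11% of bases (exact binomial p = 0.928). Gene bodies farther from a boundary held 975 (45.5%, 43.4 to 47.6) against 43.0% of bases, and 1040 (48.5%, 46.4 to 50.6) were intergenic against 50.8% (exact binomial, adjusted p = 0.0461 for each). Assembly gaps count among these bases but can hold no peak, so differences this small may come from the bases counted. Counting protein-coding genes alone, neither difference passed (38.5% against 37.1% in bodies, p = 0.195, and 59.4% against 59.9% between genes, p = 0.644, both exact binomial), and with a limit of 5000 bp the intergenic one did not (exact binomial p = 0.267). With peaks of at most 1000 bp both passed, for all genes (47.8% in bodies, exact binomial p = 0.000105, and 45.0% intergenic, p = 2.44e-06) and for protein-coding genes (40.7%, exact binomial p = 0.00293, and 56.7%, p = 0.00793). Replicate 1 peaks taken alone lay more often within 1000 bp of a boundary (7.82%, exact binomial p = 6.97e-06), while shared peaks lay less often within 1000 bp of a protein-coding boundary (2.10% against 2.96% of bases, p = 0.0182 in the exact test). The latter difference did not pass with peaks of at most 1000 bp (2.64%, exact binomial p = 0.510).

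Peaks found in 1 replicate differed in position from shared peaks in the replicate 1 list. There 198 of 2079 unshared peaks (9.52%, 8.34 to 10.9) were within 1000 bp of a gene boundary, against 134 of 2164 shared peaks (6.19%, 5.25 to 7.29; Fisher's exact p = 5.97e-05). Around protein-coding genes the shares were 5.68% and 2.08% (Fisher's exact p = 7.07e-10). In replicate 2, 34 of 626 unshared peaks (5.43%, 3.91 to 7.49) and 129 of 2164 shared peaks (5.96%, 5.04 to 7.04) were near a boundary, a difference that did not pass (Fisher's exact p = 0.699), nor did it around protein-coding genes (3.19% and 2.08%, Fisher's exact p = 0.131). With summits within 100 bp required for a shared peak, the replicate 1 difference no longer passed (p = 0.0976 in Fisher's exact test). In replicate 2 shared peaks then lay more often within 1000 bp of a boundary (6.97% against 4.37%, Fisher's exact p = 0.00425).

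Shared peaks were assigned to 1300 of 21779 protein-coding genes (5.97%). Of the 2175, 854 (39.3%) lay inside a protein-coding gene and 1575 (72.4%) inside or within 100 kb of one. These shares show no association with genes, since no share of bases was computed for them. In coding bodies more than 1000 bp from a boundary, the peak share was close to that of bases (38.5% against 37.1%).

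The Hox cluster list did not pass after adjustment in the main test (adjusted p = 0.0598 by permutation). Of its 39 genes, 4 had a shared peak, against 0.504 expected from matched random lists (permutation p = 0.00272). Among them were Hoxa2 with 2 shared peaks, Hoxa3 with 2 and Hoxb2 with 1. Peaks lay inside Hoxa2 (chromosome 6, 52163758 to 52165306, 5.84-fold in replicate 1 and 4.79-fold in replicate 2) and inside the annotated span of Hoxa3 (52172502 to 52173003, 7.92 and 4.17, and 52175328 to 52175733, 5.80 and 3.53). Another lay 2.02 kb from Hoxa2 (52166523 to 52167011, 4.97 and 5.29), within the long noncoding RNA gene Hoxaas2. Hoxb2, on chromosome 11, held a peak at 96351735 to 96352104 with 8.04- and 3.80-fold enrichment. Hoxa5 itself (52201754 to 52204587) had no shared peak. A replicate 1 peak with 4.57-fold enrichment had its summit inside it, and the nearest shared peak was 26.2 kb away. The Hox list passed with replicate 1 alone (adjusted p = 0.00088 by permutation) and with genes assigned within 10 kb (adjusted p = 0.0044 by permutation) or 1 kb (0.00176). It also passed with a −log10 q of at least 5 (adjusted p = 0.0246 by permutation) and with peaks of at most 1000 bp (0.0185), but not with replicate 2 alone (0.0717).

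TALE homeodomain proteins are DNA-binding partners of HOX proteins, and 3 of the 9 genes had a shared peak (1.33 expected, permutation p = 0.249, adjusted p = 0.783). Pbx3 had 3, the highest 80.7 kb from the gene (chromosome 2, 34090551 to 34090996) with 14.9- and 13.1-fold enrichment. Meis1 had 1 at 5.73 kb (chromosome 11, 18874468 to 18874991, 4.63 and 2.85).

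Of 27 transcription factor genes of the lung mesenchyme, 9 had a shared peak against 4.09 expected (permutation p = 0.0227), which did not pass after adjustment (adjusted p = 0.250). A peak of 30.9-fold in replicate 1 and 17.0-fold in replicate 2 (chromosome 10, 22919716 to 22920332) had Tcf21 as its nearest coding gene, 99.9 kb away and so just inside the limit. Tbx5 held 3 shared peaks, the highest at chromosome 5, 119827333 to 119827743 (12.8 and 6.09), and Tbx4, its paralogue, held 1 (chromosome 11, 85893542 to 85894086, 7.29 and 4.25). Both act in the budding lung mesenchyme. Nfib, needed for lung maturation, held 4 between 82306017 and 82447505 on chromosome 4, with 4.08- to 5.38-fold enrichment in replicate 1. This list passed with replicate 1 alone (15 members, adjusted p = 0.00836 by permutation) and with genes assigned within 10 kb (8 members, adjusted p = 0.00902 by permutation), but not with replicate 2 alone (11 members, adjusted p = 0.0717 by permutation), a −log10 q of at least 5 (0.297) or peaks of at most 1000 bp (0.0517). Within 1 kb it passed (7 members, adjusted p = 0.0163 by permutation).

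None of the 22 lists passed after adjustment in the main test, and the other 19 had adjusted p from 0.444 to 1 by permutation. Hox and mesenchyme were the 2 lists with an unadjusted p below 0.05. In the hedgehog list 5 of 15 genes had a shared peak (2.11 expected, permutation p = 0.0829). They included Disp1, the receptor gene Ptch1 (chromosome 13, 63558581 to 63558921, 4.60 and 2.65), the coreceptor gene Boc, and Smo, which encodes the signal transducer. The Smo peak reached only 2.32- and 2.47-fold, with a −log10 q of 48.9 and 82.1, and so also joined a low fold to a high −log10 q. In the cartilage list 5 of 19 genes had one (2.13 expected, permutation p = 0.0859). Runx2, a skeletal transcription factor gene, held 2, one of them with 27.2- and 15.4-fold enrichment (chromosome 17, 44557597 to 44558254). The highest replicate 1 folds at Matn3, Col2a1 and Sox6 were 2.99, 4.59 and 5.00, the last at 60.1 kb from the gene. Without matching on gene surroundings, mesenchyme, cartilage and hedgehog had more bound members than expected, olfactory receptors had fewer (9 against 66.2 expected, adjusted p = 2.75e-18), and Hox did not pass (Fisher's exact test).

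**Figure D2:**
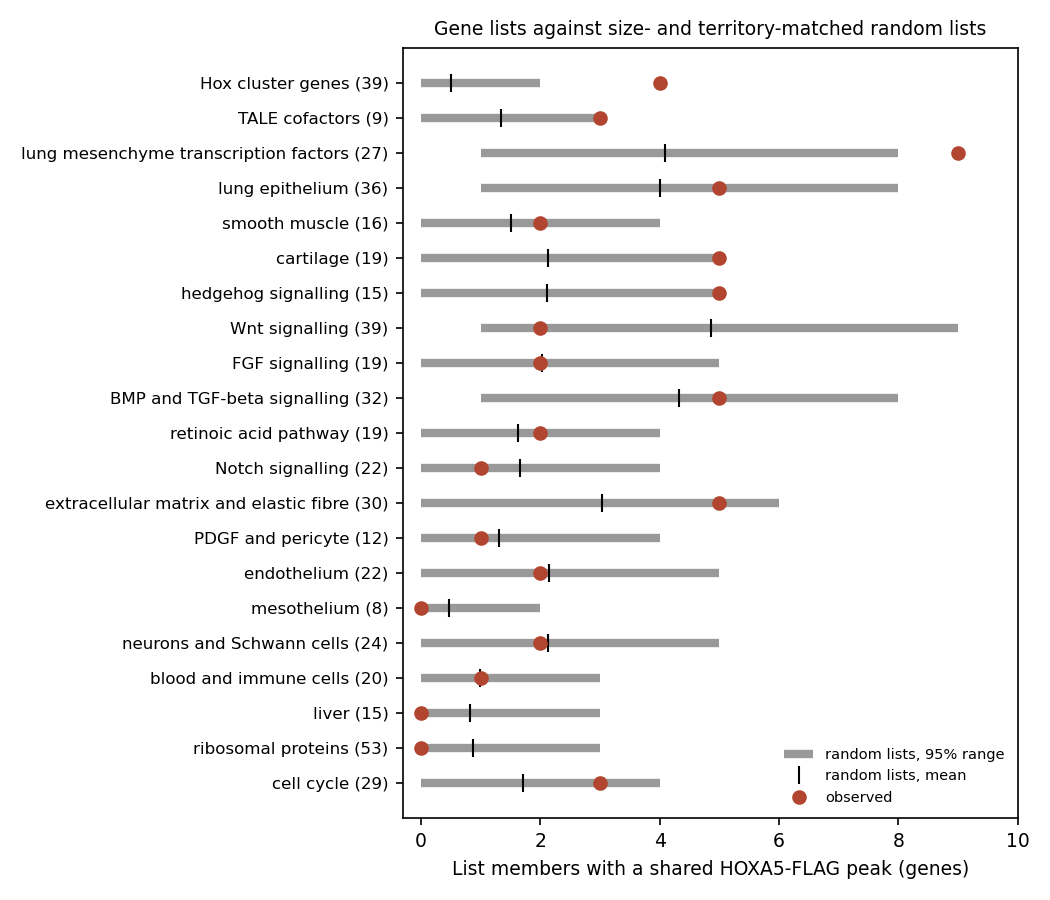
Number of members of each list with a shared HOXA5-FLAG peak (x axis, points) beside the mean (tick) and 95% range (bar) of 100000 random lists of the same size and surroundings. List sizes are in parentheses, and the olfactory receptor list of 1109 genes is not drawn. The Hox point, at 4, and the lung mesenchyme transcription factor point, at 9, lie to the right of their bars.

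Other signalling lists did not differ from their random means by the test. In the FGF list 2 of 19 genes had a shared peak (2.03 expected). One peak lay 35.2 kb from Fgf10, the mesenchymal growth factor of lung branching (chromosome 13, 118679217 to 118679877, 12.2- and 7.41-fold), and one 5.93 kb from Etv4. Of 39 Wnt genes 2 had one (4.86 expected), the receptor genes Ror1 with 3 and Ror2 with 2. In the BMP and TGF-beta list 5 of 32 had one (4.33 expected). Among them were Smad3 at 31.5 kb (10.7 and 5.38), Bmpr1b (8.68 and 5.17), Ltbp1 at 7.1 kb and Smad2 at 52.6 kb. In the retinoic acid list 2 of 19 had one (1.63 expected), inside the receptor gene Rarb (5.60 and 3.84) and 19.4 kb from Aldh1a2. Maml3 was the single bound gene of 22 Notch genes (1.66 expected).

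Among structural and cell type lists, 5 of 30 extracellular matrix genes had a shared peak (3.03 expected). The highest were near Col6a3 (33.0 kb, 13.5- and 7.63-fold), and inside Col5a2 (9.98 and 4.31) and Ltbp2 (9.74 and 5.22). Fbln1 had one at 4.78 kb. In the lung epithelium list 5 of 36 had one (4.01 expected), with Foxp1 at 10.8- and 4.78-fold, Etv4, Irx5 at 45.4 kb and Irx1 at 12.2 kb. Of 16 smooth muscle genes 2 had one (1.51 expected), Itga8 and Mylk. Of 22 endothelial genes 2 had one (2.15 expected), Erg inside the gene and Sox17 at 63.0 kb. Of 12 pericyte genes Angpt1 did (1.31 expected). Of 24 nerve genes Rbfox3 and Neurod1, the latter at 32.9 kb, did (2.13 expected), and of 20 blood genes 1 did (0.993 expected). Of 29 cell cycle genes 3 did (1.71 expected), E2f3, Cdkn1a and Cdk6. No mesothelium, liver or ribosomal protein gene had a shared peak (0.472, 0.825 and 0.878 expected), and 9 of 1109 olfactory receptor genes did (15.4 expected, permutation p = 0.101), among them Olfr957. With genes assigned within 10 kb, 1 olfactory receptor gene had a shared peak against 8.61 expected (adjusted p = 0.0158 by permutation). The olfactory list did not pass with replicate 1 alone (22 against 31.5 expected, adjusted p = 0.278 by permutation) or replicate 2 alone (14 against 19.9, 0.683). Nor did it pass with a −log10 q of at least 5 (0.391) or peaks of at most 1000 bp (0.401), and within 1 kb too few were expected (0.817) to call. With shared peaks limited to members of at most 1000 bp, no peak remained at Smo, Matn3, Erg, Sox17, Angpt1, Neurod1, Cdk6 or Cdkn1a, nor at the olfactory receptor genes Olfr1320 and Olfr1325. A −log10 q of at least 5 left none at Meis1, Smad2, Cdk6, Neurod1 or Olfr1325. Reciprocal overlap left none at Maml3, Meis1 or Olfr1325. Summits within 100 bp left none at Aldh1a2, Angpt1, Boc, Cdk6, Irx1, Neurod1, Sox17, Olfr1320 or Olfr1325.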

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

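All tests in this part were chosen after the results were seen. Unplaced or alternative scaffolds held 18 shared peaks, which no comparison with genes used, and this is a signal outside the main measurement. The longest covered 45815 bp in replicate 1, at 3.46-fold enrichment there and 2.25-fold in replicate 2.

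Shared peaks holding a member longer than 1000 bp had low fold enrichment. There were 532 of them (24.5%), with a median fold of 3.30 in replicate 1 against 4.93 for the 1643 others, and with a smaller gap in replicate 2 (3.29 against 3.80), where their median −log10 q was the higher one (12.4 against 11.8). Being the same kind of site as the others, called longer, is argued against by position only for the class as a whole. Inside a protein-coding gene lay 30.8% against 42.0% (a difference of −11.2 percentage points, Fisher's exact p = 4.14e-06). Long peaks were not matched to the others on fold or −log10 q, so this cannot tell how many of them differ in kind. They lay more often on unplaced or alternative scaffolds, by 1.14 percentage points (9 of 532 against 9 of 1643, Fisher's exact p = 0.0227), which is consistent with sequence collapsed or misplaced in the assembly for a small part of them. Extended HOXA5 binding stays open because the inputs were not analysed here, and no biological explanation was tested.

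Of the replicate 1 peaks, 2094 had no partner in replicate 2. Whether weaker enrichment in replicate 2 left some true sites below its threshold stays open. A partner for 98.0% of replicate 1 peaks of at least 10-fold against 48.3% of the others could also arise from spurious weak calls there. As an account of all unshared peaks, weaker enrichment would also need them near protein-coding boundaries as often as shared peaks of like −log10 q. The next comparison did not find that. The threshold alone is argued against, because among peaks of at most 1000 bp and within bins of −log10 q, shared peaks lay less often within 1000 bp of a protein-coding boundary than unshared ones (−5.57 percentage points, permutation p = 7e-05). Leaving out the bin above 50, with 27 unshared peaks, gave −4.23 (permutation p = 1e-05, the smallest possible), and this concerns the replicate 1 list, since in replicate 2 the protein-coding boundary shares of 2.08% and 3.19% did not differ by the test (Fisher's exact p = 0.131). It also rests on overlap by at least 1 bp. With summits within 100 bp required, the replicate 1 difference for all genes was −1.46 percentage points (Fisher's exact p = 0.0976). Protein-coding boundaries were not compared under that rule. Signal at gene ends in replicate 1 that does not come from the tag stays open, as no untagged lung was analysed here, and no biological explanation was tested.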

How the results depend on the processing

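Gene boundaries in place of transcription starts, the limit of 1000 bp on peak length, and protein-coding genes alone in the comparison with unshared peaks were chosen after seeing the data. The comparisons by fold enrichment were not planned either. The number of replicate 2 peaks with a partner, 2197, stayed within 1.5 times under reciprocal overlap, summit distance, a −log10 q of at least 5 and autosomes with X (1593 to 2165), each with a permutation p of 1e-05, and was 675 among the top 1000 peaks, where fewer peaks were tested. Local random shifts gave 18.2 overlaps on average. The share near a gene boundary, 6.02%, was 20.1% within 5000 bp, where shared peaks fell below the genome share, 2.10% with protein-coding genes, and 5.84% to 7.82% with 1 replicate left out, the highest being replicate 1 alone and above the genome share. The number of gene lists with more bound members than random lists, 0, was 2 with genes within 10 kb, 2 within 1 kb, 3 without matching, 1 with a −log10 q of at least 5, 1 with peaks of at most 1000 bp, and 0 to 2 with 1 replicate left out. Olfactory receptors had fewer within 10 kb and without matching, and did not pass in the other settings. Shared minus unshared boundary share with summits within 100 bp was −1.46 percentage points in replicate 1 and 2.60 in replicate 2. The cause of these changes was not tested. Of 52 genes selected from the lists by rank, the number of shared peaks was the same for 47 with reciprocal overlap, 39 with summits within 100 bp, 43 with a −log10 q of at least 5 and 41 with peaks of at most 1000 bp. The motif tests, matching on GC content, and transcription starts with their distances were not run, because no sequence, strand or exons were used here. No paired analysis was possible because no values of the input libraries were used. Unknown depth limits any reading of the unequal peak numbers.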

Other observations

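The tests of this part were chosen after the data were seen, and so were the genes it names. Several of the genes with the most shared peaks were long ones, with exceptions such as Gm52481 on chromosome Y (7 shared peaks, 1 of them with members of at most 1000 bp). Lrmda on chromosome 14 had 11 shared peaks over an assigned territory of 1152 kb, 9 of them with members of at most 1000 bp. Galntl6 had 6 over 1200 kb, Wwox 5 over 1019 kb and Bcas3 5 over 479 kb. Cd47, which encodes a cell surface signal against phagocytosis, had 4 over 204 kb, all of at most 1000 bp. Mecom, a transcriptional regulator gene, also had 4. Ulk4 had 6 and Apba2 had 5, of which 2 in each were of at most 1000 bp.

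Among the 200 kb windows with many shared peaks, one had no peak over 1000 bp and lay around Phlda1 on chromosome 10 (5 shared peaks, summits from 111544210 to 111696386). Windows of 7 shared peaks on chromosomes 8 and Y, and of 6 on X near Asmt, consisted mostly of peaks over 1000 bp (5, 6 and 4 of them).

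The share of peaks on X was 3.19% in replicate 1 and 4.38% in replicate 2. Among peaks of at most 1000 bp it was 2.43% and 2.87%. The lists share most replicate 2 peaks and are 1 library each, so no test of the difference between them is given. Of shared peaks with a member over 1000 bp 9.77% lay on X, against 1.89% of the others (Fisher's exact p = 5.31e-14). X makes up 6.30% of the annotated sequence.

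Gene families defined by a shared symbol stem gave no group that passed. Of 153 families of at least 15 genes tested by permutation with the same matching, 0 had an unadjusted p below 0.05. Some would be expected by chance among so many, so the test was conservative and may miss modest departures. Many families had under 1 bound member expected (0.0704 for Pcdhb), where too few could not be called. The Sema family, which encodes guidance cues, had 5 of 20 members with a shared peak against 2.28 expected (permutation p = 0.112, adjusted p = 1).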
